A study of Caenorhabditis elegans with 9 samples.

How the data were processed

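Total RNA of whole L2 larvae was measured by RNA-seq in 9 libraries, 3 each of wild type (N2), of homozygous hsf-1(ok600) and of hsf-1(ok600) carrying the transgene rmSi1[hsf-1::gfp] (strain AM1061). Per the labels' protocols, each library came from 500 larvae pooled over several collections, 30 h after a 2 h egg lay, the stated temperature was 20 °C, and the homozygous mutants were picked as GFP-negative offspring of a strain balanced with hT2, which rearranges chromosomes I and III. Per the labels' protocols, RNA was extracted with Trizol and a column kit with DNase digestion, and libraries were made with the Nugen Ovation RNA-Seq V2 kit (SPIA amplification). Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the libraries of a genotype were grown as separate cultures, so the deposited p-values measure the spread between these libraries.

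The FPKM values were made by the authors with TopHat2 and Cuffdiff on the build ce10, per the submitters' processing notes, and versions, annotation, filters and the strand setting of counting are not given in the sources used here. Per the file headers, an FPKM with a lower and an upper bound is given per gene and genotype, so the libraries of a genotype were combined by the authors before deposit. The level of the bounds is not stated. They are symmetric about the value for most genes, and in 32, 49 and 39 of 20348 genes of wild type, mutant and transgenic line the value lies outside its own bounds. The p-values and q-values were deposited by the authors for the mutant against wild type, per the file headers, with 12615 genes tested, 7736 marked as not tested and 38 with too little or too much data. The FPKM values in the deposited test table differ in scale from those of the table of all genotypes (median ratio 1.04 in wild type), and the levels printed here are from the latter. In the files 6 gene symbols read as dates and 283 fold changes as an error text, so genes were matched by sequence name and fold changes computed again. Current symbols were found for 19879 of 20389 sequence names in the RefSeq gene table of WBcel235, whose release is not given in the sources used here, and exonic lengths were taken from Ensembl release 115. Coordinates are those of the files on ce10, where genes that overlap can share a locus, and the start and end then span all of them.

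Designs, gene lists, named genes and most alternatives were fixed before the data were examined. The design planned a moderated linear model on values per replicate and named the fallback used here, since the tables hold 1 value per genotype. In the mutant against wild type, a gene was called at a deposited q of at most 0.05 with an FPKM of at least 1 in at least 1 group. For the other comparisons, genes were counted whose deposited intervals did not overlap, among genes with an FPKM of at least 1. Log2 differences were taken of FPKM with a pseudocount of 1, which understates the change of low genes, while folds are ratios of FPKM as deposited. The share of called genes nearer to wild type in the transgenic line was computed on the log2 scale, with the midpoint at 0.5 of the change, and an exact (Clopper-Pearson) binomial interval. For 31 lists, hsf-1 alone being one, the median log2 difference was set against 10000 random lists of the same size drawn from the tested genes within 20 bins of mean expression. In every comparison the mean was that of wild type and the mutant, and the tested genes were those of the deposited test. Comparisons with the transgenic line were therefore not matched on its own expression. Deposited p-values were also adjusted by the Benjamini-Hochberg method within each list.

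The text names hsf-1, members of the cytosolic chaperone, CCT and heat-inducible lists, up to 4 called members of each other list with the largest log2 difference, and the 10 called genes with the largest rise and the largest fall, the latter groups among genes with an FPKM of at least 5 in at least 1 group. Genes named outside this rule are marked as chosen after their values were seen.

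The interval rule and the list percentiles were tested on simulated data for the mutant against wild type over 12612 genes, drawn with 2 standard errors per half-width of the deposited interval, which is assumed. With 200 genes changed 2-fold, 4-fold or 8-fold, the interval rule found 8%, 37.5% and 71% of them (16, 75 and 142), beside 260, 233 and 228 unchanged genes. List shifts of 1 on the log2 scale lay in the lowest or highest 2.5% of random lists in 20 of 20 lists, shifts of −0.5 and 0.5 in 12 and 13 of 20, and unshifted lists in 1 below and 2 above of 20. The same error model, in 50 simulations, gave the counts and shares printed beside the observed ones. Alternatives were pseudocounts of 0.1 and 0.01, no filter or a minimum FPKM of 5, a q of at most 0.01, an absolute log2 fold change of at least 1, centring on genes with an FPKM of at least 5 in every genotype, adjustment within the filtered genes, and random lists matched on length too or unmatched. Leaving out genes listed at 0, and genes in a shared locus, were added after seeing the data. Sequence composition was not examined, as no genome sequence was used here. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.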

Results

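RNA was sequenced from whole Caenorhabditis elegans larvae of the L2 stage in 3 genotypes: wild type (strain N2), a mutant homozygous for ok600, a deletion allele of the heat shock transcription factor gene hsf-1, and the same mutant carrying an hsf-1::gfp transgene (rmSi1), called the transgenic line here. Each genotype had 3 libraries, 9 in all, and each library came from a pool of 500 larvae brought together from several collections, 30 h after eggs had been laid in a window of 2 h. The stated temperature was 20 °C and no heat shock was named. The mutant larvae were offspring of a balanced strain (OG576) and were picked for lacking the GFP of the balancer chromosome.

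The deposited tables hold 1 FPKM value per gene and genotype, made by the authors from the 3 libraries together, so no spread between libraries can be given here. The error printed beside a value is the interval the authors deposited with it, whose level is not stated. Of 20389 genes listed, 11851 had an FPKM of at least 1 in wild type, 12783 in the mutant and 11852 in the transgenic line, and 5423, 3458 and 4550 were listed at 0. The sequencing depth is unknown, because FPKM does not keep it. At an FPKM of 20 or more, the median half-width of the interval was 67.6% of the value in wild type, 64.6% in the mutant and 67.7% in the transgenic line.

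The targeted gene was looked at first. hsf-1 (Y53C10A.12, ce10 chromosome I, 11953502 to 11961977) was listed at an FPKM of 25.3 (interval 7.62 to 43.1) in wild type, 21.4 (6.52 to 36.4) in the mutant and 69.3 (29.4 to 109) in the transgenic line. The log2 difference of the mutant from wild type was −0.23, with a q of 0.749 in the authors' deposited table. A value for the whole gene does not check the deletion, since RNA from the remaining part of the gene counts as hsf-1, and so does RNA of the transgene. The value of the transgenic line was 2.74-fold that of wild type and 3.23-fold that of the mutant, and its interval overlapped both others.

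The comparison of the mutant with wild type asks which RNAs differ in larvae homozygous for the hsf-1 deletion allele when no heat shock is named. Several abundant cytosolic chaperone genes fell. The constitutive Hsp70 gene hsp-1 fell 6.58-fold, from an FPKM of 2492 (interval 1587 to 3399) to 379 (202 to 556), and the Hsp90 gene daf-21 fell 5.36-fold, from 2062 (1217 to 2907) to 385 (213 to 557). The fall of sti-1, whose product links Hsp70 with Hsp90, was 7.49-fold, from 47.8 (16.8 to 78.7) to 6.38 (0.649 to 12.15). Most CCT chaperonin subunit genes and some genes for mitochondrial chaperones and lipid metabolism fell in the same larvae, while some autophagy and defence genes rose.

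Of the 20 tested genes on the list of cytosolic chaperones and cochaperones, 11 fell, 0 rose and 9 did not pass in the authors' deposited table, and 12 fell when the deposited p-values were adjusted over the list alone. Besides hsp-1 (F26D10.3, chromosome IV, 17278920 to 17281298), daf-21 (C47E8.5, chromosome V, 14680299 to 14688528) and sti-1 (R09E12.3, chromosome V, 773551 to 774859), these were the Hsp110 gene hsp-110, the J-domain genes dnj-11, dnj-12, dnj-13 and dnj-19, and the Hsp90 cochaperone genes fkb-6, ahsa-1 and daf-41. Among the J-domain genes, dnj-19 went from 236 (119.6 to 352) to 70.5 (27.4 to 113.5) and dnj-13 from 384 (190.2 to 579) to 119.6 (49.8 to 189). The locus of daf-21 in the files is shared by 3 genes and that of dnj-13 by 5. The Hsp90 cochaperone gene cdc-37 was at 147 and 101 FPKM and the myosin chaperone gene unc-45 at 14.7 and 9.58, with q-values of 0.234 and 0.376 in the authors' deposited table. The median log2 difference of the list was −1.16, below that of every one of 10000 random lists of the same size matched on expression (percentile 0). Such percentiles describe these libraries and are not p-values, and a place between the lowest and the highest 2.5% is called inside the bounds.

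The CCT chaperonin folds tubulin and actin, and prefoldin delivers them to it. Of the 14 genes of this list, 8 fell, 0 rose and 6 did not pass in the authors' deposited table, and 10 fell when adjusted over the list alone. The 8 were cct-1 to cct-7 and pfd-6, and cct-8 was at 64.1 in wild type and 33.7 in the mutant, with a q of 0.062 in the authors' deposited table. The subunit gene cct-3 (F54A3.3, chromosome II, 2233545 to 2243576) fell 3.51-fold, from 108 (56.8 to 159.6) to 30.9 (11.9 to 49.5), and cct-4 (K01C8.10) fell 3.04-fold, from 274 (149 to 399.8) to 90.3 (41 to 139.5). The median log2 difference of the list was −1.14, again below all 10000 matched lists.

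**Figure D1:**
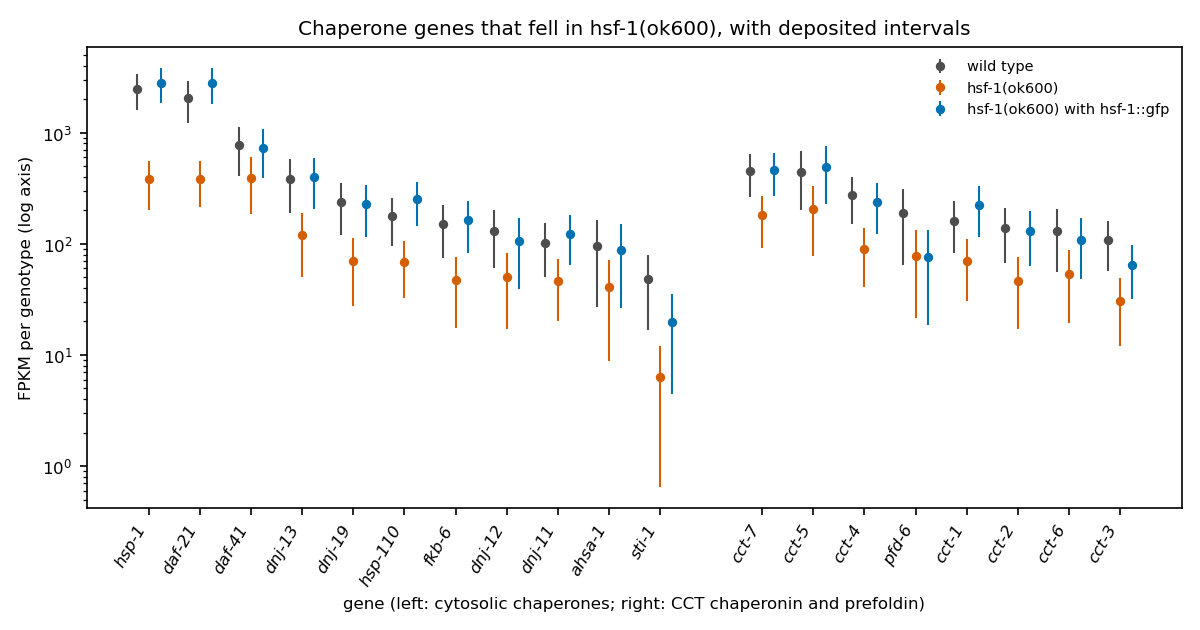
FPKM per genotype on a log axis for the 11 cytosolic chaperone genes (left) and the 8 CCT and prefoldin genes (right) that fell in hsf-1(ok600), where points are the authors' values over 3 libraries and bars their deposited intervals. For hsp-1 the mutant lies at 379 while wild type and the transgenic line lie at 2492 and 2819.7, and pfd-6 lies at 76.5 in the transgenic line, beside 77.5 in the mutant.

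Few of the heat-inducible and small heat shock genes passed. Of 19 on the list, 9 were tested, 2 rose and 0 fell in the authors' deposited table, with the same counts when adjusted over the list alone. The risers were the small heat shock protein genes sip-1, from 15.8 (2.49 to 29.1) to 88.7 (27.1 to 149), and hsp-43, from 47.3 (12.5 to 82.1) to 108 (44.7 to 171). The classical stress gene hsp-16.2 was listed at 97.1 (23.2 to 169.6) in wild type and 0.857 (0 to 2.88) in the mutant, and hsp-70 (C12C8.1) at 8.05 (0.412 to 15.6) and 0.176 (0 to 0.793). Neither passed, with q-values of 0.437 and 0.328 in the authors' deposited table. The near-identical genes hsp-16.1, hsp-16.11, hsp-16.48 and hsp-16.49 were listed at 0 in every genotype, and reads shared between hsp-16 copies make the value of each copy uncertain. The locus of hsp-16.2 in the files is shared by 4 genes, hsp-16.41 among them. The list's median log2 difference was −0.27, at percentile 9.84, but 1.17, at percentile 98.2, over the 3 genes in a locus of their own.

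Of 20 genes for mitochondrial chaperones, proteases and protein import, 6 fell and 0 rose in the authors' deposited table, and 9 fell when adjusted over the list alone. The matrix Hsp60 gene hsp-60 (Y22D7AL.5, chromosome III, 1619733 to 1625911) fell 3.45-fold, from 717 (426 to 1008) to 208 (103 to 312), and its neighbour Y22D7AL.10 fell 2.98-fold, from 1089.8 (557 to 1624) to 365 (149.6 to 582). The mitochondrial Hsp70 gene hsp-6 (C37H5.8) fell 2.51-fold, from 513 (324 to 702) to 204 (118 to 289.6). The list's median was −0.80, at percentile 0. In contrast, none of the 18 tested genes for protein folding and stress in the endoplasmic reticulum passed in the authors' deposited table, and 0 passed when adjusted over the list alone, with a median of −0.10 at percentile 26.9. This holds for the list alone. The genes sec-61.A, sec-61.B and trap-1 to trap-4, chosen after their values were seen, are not on it and fell in the authors' deposited table. Their deposited log2 fold changes lay between −0.65 and −1.84.

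The lipid lists lay lower, with a minority of their genes past the test. Of 26 genes for fatty acid synthesis and desaturation, 6 fell and 1 rose in the authors' deposited table, and 10 fell and 1 rose when adjusted over the list alone. The elongase gene elo-6 (F41H10.8, chromosome IV, 5386619 to 5388553) fell 5.16-fold, from 111 (37.5 to 185) to 21.6 (3.15 to 40.02), elo-2 fell 3.04-fold, from 225 (98.7 to 351) to 74.0 (22.9 to 125), and the stearoyl-CoA desaturase gene fat-6 fell 2.91-fold, from 237 (103 to 372) to 81.6 (25.5 to 138). The median was −0.52, at percentile 0.05. For fatty acid oxidation and lipolysis, 4 of 20 genes fell and 0 rose in the authors' deposited table, and 9 fell and 1 rose when adjusted over the list alone. The acyl-CoA dehydrogenase gene acdh-1 (C55B7.4, chromosome I, 6497440 to 6499561), which acts in the breakdown of propionate, fell 3.92-fold, from 1433 (902 to 1964) to 366 (204 to 527), and the carnitine palmitoyltransferase gene cpt-4 fell 2.70-fold, from 130.0 (69.4 to 190.1) to 48.2 (21.5 to 74.7). This list's median was −0.74, at percentile 0.

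Among genes of oxidative phosphorylation and the TCA cycle, 4 of 61 fell and 0 rose in the authors' deposited table, also when adjusted over the list alone, with a median of −0.27 at percentile 0.09. The ATP synthase subunit gene asb-1 went from 131 (54.3 to 207) to 49.8 (17.8 to 81.4), and the complex I subunit gene nuo-2 from 204 (89.96 to 319) to 99.0 (35.9 to 162). Of 25 genes for glycolysis, gluconeogenesis and glyoxylate metabolism, 2 fell and 0 rose in the authors' deposited table, and likewise when adjusted over the list alone. They were the aldolase gene aldo-2, from 755 (447 to 1063) to 389.7 (211 to 568), and the glycogen phosphorylase gene pygl-1, from 277 (159 to 394.8) to 153 (78.9 to 227), and the list's median was −0.17, at percentile 9.80.

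Genes for making ribosomes and copying DNA lay lower as groups, with few single genes past the test. Of 26 ribosome biogenesis genes, 3 fell and 0 rose in the authors' deposited table, 7 and 0 when adjusted over the list alone, and the median was −0.57, at percentile 0.03. The box C/D snoRNP genes fib-1, from 820.5 (478 to 1163) to 394 (196 to 592), and nol-5, from 396 (214 to 577) to 199.6 (95.6 to 304), and the nucleolin gene nucl-1 were those that fell. Of 56 genes for DNA replication and the cell cycle, 3 fell and 0 rose in the authors' deposited table, with the same counts when adjusted over the list alone and a median of −0.30 at percentile 0.11. The 3 were the replicative helicase genes mcm-4 and mcm-7 and the ribonucleotide reductase gene rnr-2, of which mcm-7 went from 51.3 (21.6 to 81.1) to 21.3 (6.23 to 36.4). Of 30 tested histone genes, 1 fell, his-6, and 1 rose, his-72, in the authors' deposited table, also when adjusted over the list alone, with a median of −0.60 at percentile 0, and of 0 without a filter. The histone his-72 encodes an H3.3 variant, which is made outside of DNA replication as well, and reads shared between near-identical histone copies make single histone values uncertain.

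Cytosolic ribosomal protein genes stayed close to the wild-type level as a group. Of 79 tested, 4 rose and 2 fell in the authors' deposited table, 6 and 2 when adjusted over the list alone, and the median was −0.01, at percentile 44.4, with its sign turned (0.01) after centring each genotype on its median. The stalk protein genes rla-0 and rla-1 rose, rla-0 from 1199 (699 to 1698) to 2110.0 (1271 to 2949), while rpl-39 and rpl-36 fell. Of 61 translation factor and tRNA synthetase genes, 1 fell (inf-1) and 1 rose (sars-1) in the authors' deposited table, 1 and 0 when adjusted over the list alone, and the median was −0.19, at percentile 1.41, but inside the bounds among genes in a locus of their own. None of the 33 proteasome genes passed in the authors' deposited table or when adjusted over the list alone (0), although 26 lay higher and the median was 0.29, at percentile 98.1, but inside the bounds with length matching, with unmatched lists and among genes in a locus of their own.

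Some autophagy genes rose, while most of their list did not pass. Of 27 genes for autophagy, ubiquitin and the lysosome, 8 rose and 0 fell in the authors' deposited table, and 11 and 0 when adjusted over the list alone, with a median of 0.43 at percentile 99.6. The median was no longer in the highest 2.5% against unmatched lists (percentile 95.3) or among genes in a locus of their own (0.35, percentile 95.5). The ubiquitin-like gene lgg-1 (C32D5.9, chromosome II, 6346925 to 6347689) encodes a worm member of the LC3 and GABARAP family. It rose 3.45-fold, from 125 (37 to 213) to 431 (208 to 654). The autophagy receptor gene sqst-1 (T12G3.1, chromosome IV, 12034230 to 12037029) rose 2.74-fold, from 50.4 (23.2 to 77.8) to 138 (75.9 to 200.2), and atg-13 (D2007.5), for a part of the kinase complex that starts autophagy, rose 4.27-fold, from 10.1 (0.185 to 20.3) to 43 (13.5 to 72.5). Of these, the intervals of the mutant and wild type overlapped in all 3.

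Secreted defence proteins moved both ways. Of 93 tested C-type lectin genes, 7 rose and 2 fell in the authors' deposited table, 7 and 3 when adjusted over the list alone, with a median of 0.51 at percentile 99.3, but inside the bounds without a filter and among genes in a locus of their own. The lectin gene clec-60 (ZK666.6, chromosome II, 10480042 to 10481786), an intestinal gene induced by some bacterial infections, was at 1.11 (0 to 2.37) in wild type and 546 (299 to 791) in the mutant. Of 63 antimicrobial effector genes, 5 rose and 6 fell in the authors' deposited table, 7 and 8 when adjusted over the list alone, with a median of 0.18 at percentile 85.5. The saposin-like gene spp-2 rose 6.75-fold, from 14.4 (0.952 to 27.8) to 97.3 (20.7 to 173), spp-9 and spp-21 were listed at 0 in wild type and at 11.6 and 12.96 in the mutant, and the invertebrate lysozyme gene ilys-5 (F22A3.6) fell 6.35-fold, from 1103 (587 to 1620.4) to 174 (54.7 to 293). Among 127 cytochrome P450, glutathione transferase and glucuronosyl transferase genes, 1 rose (cyp-14A5) and 4 fell in the authors' deposited table, 1 and 2 when adjusted over the list alone. Their median of −0.02 lay at percentile 0.36, since matched lists had a median of 0.24, and it was 0.00 after centring and inside the bounds with unmatched lists. The transferase gene ugt-22 fell 5.25-fold, from 121 (58.1 to 184) to 23.1 (6.70 to 39.5).

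Cuticle collagen genes lay higher as a group. All larvae were collected 30 h after the egg lay, and whether the genotypes were equally far developed was not examined. For this list, and for those of moulting, histones and DNA replication, a difference in stage therefore cannot be told apart from one of genotype. Of 107 tested cuticle collagen genes, 8 rose and 1 fell in the authors' deposited table, 12 and 1 when adjusted over the list alone, with a median of 0.40 at percentile 99.98. Examples are col-172, from 28.5 (1.08 to 56.8) to 86.2 (16.43 to 156), and col-161, from 25.9 (5.48 to 46.0) to 71.9 (25.3 to 118). Of 64 moulting and epidermis genes, 3 rose and 1 fell in the authors' deposited table, 3 and 3 when adjusted over the list alone, with a median of 0.28 at percentile 98.0, a place in the highest 2.5% that was lost with no filter, with a minimum FPKM of 5, with length matching and with unmatched lists. The collagen prolyl hydroxylase gene phy-2 went from 95.1 (39.7 to 150.6) to 173 (87.5 to 258), and the hedgehog-related gene grd-6 fell from 38.1 (13.5 to 62.6) to 15.6 (3.89 to 27.4). Of 28 neuron genes, 4 rose and 0 fell in the authors' deposited table, 4 and 1 when adjusted over the list alone, with a median of 0.36 at percentile 94.2, inside the bounds. They were the synaptobrevin gene snb-1, from 303 (141 to 464) to 624 (296 to 897), ida-1, of dense core vesicles, and the neuropeptide-processing genes egl-3 and egl-21. Of 52 neuropeptide genes, 1 rose and 0 fell in the authors' deposited table, also when adjusted over the list alone, with a median of 0.30 at percentile 96.8, inside the bounds as well. It was ins-22, listed at 0 in wild type and at 5.56 (0 to 10.802) in the mutant.

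Of 24 intestine genes, 5 fell and 1 rose in the authors' deposited table, 5 and 3 when adjusted over the list alone, with a median of −0.18 at percentile 8.15. The aspartyl protease gene asp-1 fell 2.35-fold, from 2003 (1282 to 2724) to 852 (458 to 1247), and the cathepsin B-like gene cpr-4 rose from 169 (80.2 to 257) to 322 (168 to 474). Of 30 body-wall muscle genes, 1 rose in the authors' deposited table, the integrin gene pat-3, and 0 when adjusted over the list alone, with a median of 0.05 at percentile 64.5. None of 16 pharynx genes passed in the authors' deposited table or when adjusted over the list alone (0), with a median of −0.20 at percentile 10.76. Of 36 germ line genes, 1 fell in the authors' deposited table, the meiotic cohesin gene rec-8, and 0 when adjusted over the list alone, with a median of 0.12 at percentile 32.96. The 6 tested genes of adult reproduction, yolk and sperm genes, held 0 that passed in the authors' deposited table and 0 when adjusted over the list alone, with a median of 0.51 at percentile 39.8. Of 16 targets of the longevity factor DAF-16 and antioxidant genes, 1 fell, gst-10, in the authors' deposited table and when adjusted over the list alone, with a median of −0.12 at percentile 21.9. None of 12 heterochronic genes, which time larval stages, passed in the authors' deposited table, 1 fell when adjusted over the list alone, and the median was 0.11, at percentile 66.2.

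**Figure D2:**
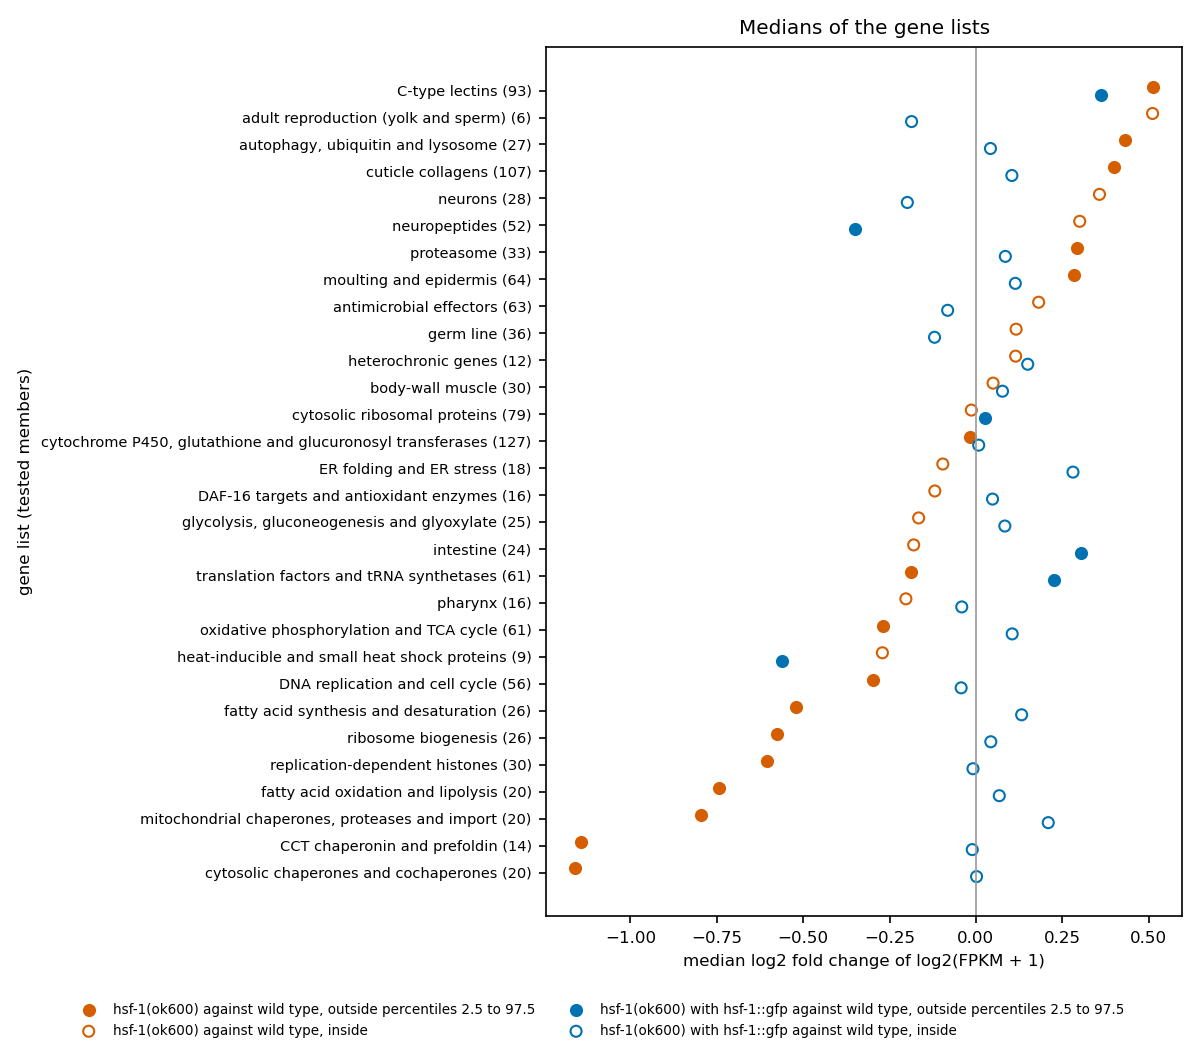
Median log2 fold change of log2(FPKM + 1) for 30 gene lists, with the number of tested genes in brackets, in hsf-1(ok600) against wild type (orange) and in the transgenic line against wild type (blue). Filled points lie in the lowest or highest 2.5% of 10000 expression-matched random lists and no error bar is drawn; cytosolic chaperones lie at −1.16 in the mutant and 0.00 in the transgenic line.

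The single genes with the largest falls were mostly at low or moderate levels in wild type. B0304.2 fell 46.9-fold, from 64.7 (13.5 to 116) to 1.38 (0 to 2.66), the aspartyl protease gene asp-12 fell 13.7-fold, from 95.04 (30.7 to 159.9) to 6.94 (0.102 to 14.3), and Y94H6A.10 (chromosome IV, 2709898 to 2710668) fell 11.6-fold, from 514 (239 to 756) to 44.1 (11.9 to 76.2). The haem transporter gene hrg-4 went from 29.8 (0.222 to 60.9) to 2.05 (0 to 4.89), and the telomere-binding protein gene pot-2 and its neighbour btb-19 fell to 2.68 and 0.958, while F38A5.8 was listed at 0 in the mutant. C52B11.5, F44E2.9 and the cyclophilin gene cyn-2 complete the 10, with falls of 14.9, 11.6 and 12.8-fold. The largest rises, besides clec-60 at 491-fold, included the beta-tubulin gene tbb-6 (T04H1.9, chromosome V, 12261785 to 12263826), from 0.708 (0 to 2.07) to 124 (59.1 to 189.5), the lipase gene lips-11, from 1.31 (0 to 2.58) to 112.3 (42 to 182), and C08E8.4, from 1.62 (0 to 3.505) to 103.96 (37.2 to 169). Rises of 35.2, 23.7 and 33.2-fold were found for srw-86, Y37H2A.14 and H02F09.3, and B0563.9, Y38H6A.5 and nspe-6 were listed at 0 in wild type. The mutant value of B0563.9 was 331 and that of Y38H6A.5 was 51.97, and both lay outside their own deposited intervals, which ended at 222 and 34.1.

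Across all genes, the authors' deposited table tested 12615 and called 735 at a q of at most 0.05, 369 higher and 366 lower in the mutant, which is 5.83% of those tested. The median FPKM of the higher genes was 23 in wild type and 69.9 in the mutant, and that of the lower genes 104.6 and 39.1. In the authors' deposited table, 253 genes shared the smallest q of 0.00249, set by the smallest p of 5e-05, and at a q of at most 0.01 the count was 353, with 190 higher and 163 lower. Of the 735, 96 lie in a locus that the files share among several genes, and 75 were listed at 0 in one of the groups, 63 in wild type and 12 in the mutant.

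Comparing the mutant with the transgenic line asks which RNAs differ between animals that share the mutation. They differ by the transgene, but also by strain, and the mutant larvae were picked offspring of mothers with the balancer. The design does not separate these differences. The cytosolic chaperone and CCT lists again lay lower in the mutant as groups, though single members such as pfd-6 did not. The value of hsp-1 was 7.44-fold higher in the transgenic line, at 2819.7 (1827 to 3813) against 379 (202 to 556), and that of daf-21 was 7.28-fold higher, at 2802 (1793 to 3813) against 385 (213 to 557). The intervals were also apart for hsp-60 (667 and 208), hsp-6 (662 and 204), elo-6 (175 and 21.6), fat-6 (436 and 81.6) and acdh-1 (1278 and 366), all lower in the mutant, and for sqst-1 (45.1 and 138) and clec-60 (1.95 and 546), which were higher there. For lgg-1 and atg-13 the values were 162 and 431 and 10.7 and 43, with overlapping intervals. The list medians of the mutant against the transgenic line were −1.11 for cytosolic chaperones (percentile 0), −1.04 for CCT and prefoldin (percentile 0), −0.78 for mitochondrial chaperones (percentile 0.02) and −0.70 for the intestine (percentile 0). Autophagy genes had a median of 0.52 at percentile 99.8 (inside the bounds with unmatched lists), neuron genes 0.53 at percentile 99.5 and neuropeptide genes 0.75 at percentile 100.

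The deposited test used here covers the mutant and wild type alone, so in this pair genes were counted by whether their deposited intervals were apart. Of 13071 genes with an FPKM of at least 1, 179 had intervals apart, 90 higher and 89 lower in the mutant. Leaving out genes listed at 0 in either group, 167 were apart, where simulated pairs without any difference gave a mean of 133.6, between 107 and 165. At a mean FPKM of at least 100, 50 of 1493 genes were apart, 38 of them lower in the mutant, where such simulations gave 26.9 on average, between 18 and 39. The simulations took the half-width of an interval as 2 standard errors, which is assumed. They scaled each interval to the drawn value, which narrows the intervals of low draws.

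Comparing the transgenic line with wild type asks how near that line lay to the wild-type state. Chaperone RNA lay near the wild-type values: hsp-1 was 1.13-fold, daf-21 1.36-fold, hsp-60 0.931-fold and hsp-6 1.29-fold the wild-type value, each with overlapping intervals. The median log2 difference of cytosolic chaperones was 0.00, at percentile 36.9, that of CCT and prefoldin −0.01, at percentile 37.1, and that of mitochondrial chaperones 0.21, at percentile 92.3. Some members lay further from wild type in either direction, among them sti-1, at 20.0 (4.45 to 35.4) against 47.8 (16.8 to 78.7) in wild type, and pfd-6, at 76.5 (18.6 to 134.1) against 189.7 (64.8 to 310.4), bag-1, at 37.9 (0 to 111.2) against 90.2 (0 to 197.4), and pfd-5, at 376.8 (130.7 to 623) against 163 (52.9 to 273), again with overlapping intervals. The stress gene hsp-16.2 was lower, at 10.5 (0.359 to 20.7) against 97.1 (23.2 to 169.6), with intervals apart, and hsp-70 was at 0.588 (0 to 2.18) against 8.05 (0.412 to 15.6). The heat-inducible list had a median of −0.56 at percentile 0.965, neuropeptides −0.35 at percentile 0.32, C-type lectins 0.36 at percentile 100, translation factors 0.23 at percentile 99.1 and the intestine 0.30 at percentile 97.8. For ribosomal proteins the median of 0.03 lay at percentile 1.82. Of these, only the translation factors kept their place under every alternative: without a filter the heat-inducible genes, neuropeptides, C-type lectins and ribosomal proteins lay inside the bounds, and with length matching the heat-inducible genes, neuropeptides, ribosomal proteins and the intestine did.

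Intervals were apart in 86 of 12563 genes, 70 higher and 16 lower in the transgenic line, and in 73 when genes listed at 0 in either group were left out. Simulated pairs without any difference gave a mean of 117 such genes, between 99 and 136. At a mean FPKM of at least 100, 5 of 1488 genes were apart, all higher in the transgenic line, where simulations gave 24.7. For the mutant against wild type, the same rule gave 117 of 13182 genes, 82 higher and 35 lower. Of the 117, 81 were also called in the authors' deposited table, and 101 remained without genes listed at 0, beside a simulated mean of 134.2, between 110 and 159. At a mean FPKM of at least 100, 28 of 1430 were apart, 8 higher and 20 lower in the mutant. Simulated pairs gave 23.04 there, between 15 and 36. The counts of 101 and 73 lie below the lowest simulated ones, so for these pairs the assumed error gives more genes apart than were found. Simulated intervals were scaled to the drawn value, which narrows those of low draws. For these pairs the simulations therefore cannot show whether more genes were apart than chance gives.

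The 735 genes called in the mutant were then followed in the transgenic line, to see on which side they lay. On the scale of log2(FPKM + 1), 519 (70.6%, exact 95% binomial interval 67.2 to 73.9) were nearer to wild type than to the mutant. The interval treats genes as independent, which they are not. Of the genes that rose, 276 of 369 (74.8%) were nearer to wild type, and of those that fell, 243 of 366 (66.4%). The median share of the change that was undone was 0.77, with 0.78 for genes that rose and 0.76 for those that fell. Their median FPKM in the transgenic line was 31.3 for the higher genes and 82.0 for the lower ones. Clear returns were clec-60, from 546 back to 1.95, tbb-6, from 124 to 2.14, and Y94H6A.10, from 44.1 to 368. C52B11.5, btb-19, cyn-2 and pot-2 stayed at 4.17, 0.346, 0.728 and 0.452, with intervals apart from wild type. The other 216 genes were nearer to the mutant, and 148 of the 735 differed at least 2-fold from wild type in the same direction in both genotypes.

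Because the genes were picked for a difference between wild type and the mutant, chance alone moves an independent genotype towards the middle. Simulated with the assumed error, the share nearer to wild type was 47.7% on average (42.9 to 51.4) when no gene differed, 20.0% (16.6 to 22.7) when the transgenic line equalled the mutant and 82.4% (78.9 to 85.9) when it equalled wild type. The observed 70.6% lay between the last pair, and it was 80.5% (284 of 353) for genes with a q of at most 0.01 in the authors' deposited table. The simulated shares are for 735 picked genes and were not computed for the stricter 353, so 80.5% cannot be set against them. Wild type, the mutant and the transgenic line were separate strains, so strain and genotype were not separated by the design.

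**Figure D3:**
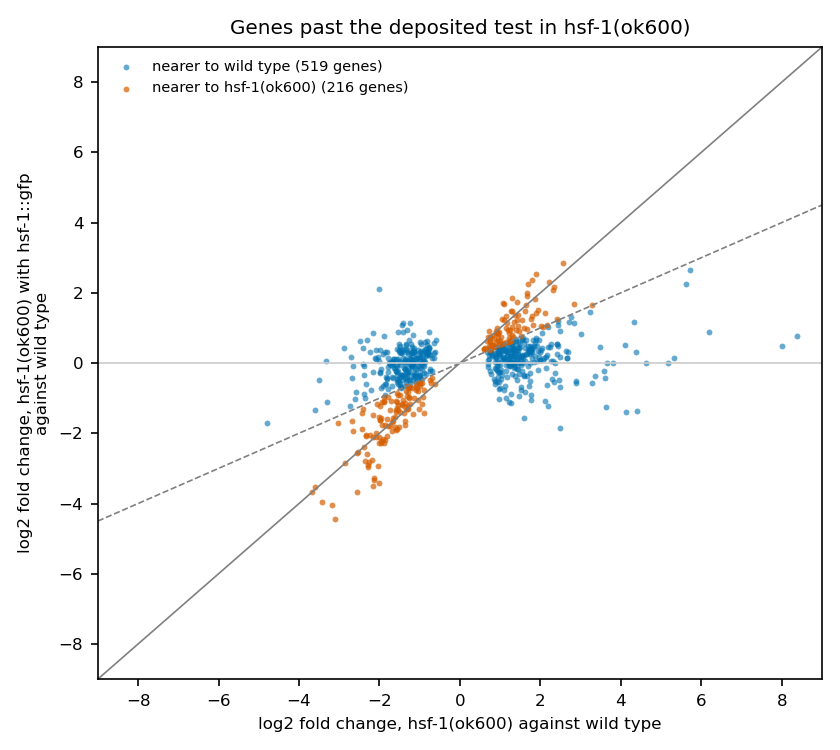
Log2 fold change of log2(FPKM + 1) against wild type in the mutant (horizontal axis) and in the transgenic line (vertical axis) for the 735 genes past the deposited test, where each point is a gene, the solid diagonal marks equal change in both and the dashed line 0.5 of that change. Blue points (519) lie nearer to wild type and orange points (216) nearer to the mutant.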

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

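The tests of loss of hsf-1 function, of genes on chromosome I, of measurement error, of culture or strain differences, of heat exposure and of an uneven library were chosen only after the results they bear on were seen.

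Among the 7736 genes that the authors did not test, 14 had an FPKM of at least 5 in the transgenic line with a lower bound above the upper bound of wild type. The test covered wild type and the mutant, so a gene high in the transgenic line alone is untested by construction, and no chance count was computed. The highest were C11D2.1 at 133.9 (interval 2.43 to 168), T22E5.7 at 124 (2.40 to 161), the invertebrate lysozyme gene ilys-3 at 60.2 (7.38 to 112.6), oac-27 at 47.8 (13.4 to 82.2) and sdz-19 at 30.1 (1.81 to 58.3), with wild-type values of at most 0.286. They were chosen after their values were seen.

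The lower level of the cytosolic chaperone and CCT lists in the mutant, with a median log2 difference of −1.15 over 34 genes, was set against technical explanations. A scaling that lowers all genes of their level is argued against, since the lowest median among 10000 lists matched on expression was −0.50, and so is gene length together with expression, with a lowest median of −0.57. Reads of neighbours in merged loci are argued against too, since the 22 members in a locus of their own had a median of −1.22. Loss of hsf-1 function is a candidate explanation that goes with the values, because in the transgenic line the median against wild type was −0.0106. Differences between the strains other than hsf-1 that the transgene does not touch, and GC content, were not tested.

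The 216 called genes that were nearer to the mutant than to wild type in the transgenic line form the next pattern. On chromosome I, that of hsf-1, lie 14.4% of them (exact 95% binomial interval 9.96 to 19.7), beside 14.7% of all called genes. With 108 called genes on that chromosome, it could not have held most of the 216. This share therefore cannot test a background linked to hsf-1 as their main source. Of the called genes, 28.7% on chromosome I and 29.5% on the others were nearer to the mutant (Fisher's exact test, p 0.909). These values argue against an excess over that chromosome as a whole. Genes close to hsf-1 were not examined apart, and effects of a linked variant on genes elsewhere were not tested. Measurement error after picking the genes stays open: simulated full return gave no share nearer to wild type under 78.9%, against the observed 70.6%, but the error was assumed. A difference in culture, strain or library that sets wild type apart from both others cannot be told apart from incomplete rescue, as 148 genes differed at least 2-fold in the same direction in both and each genotype was 1 strain.

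The stress genes hsp-16.2 and hsp-70 were higher in wild type than in both other genotypes. Heat exposure of the wild-type larvae strong enough to raise the cytosolic chaperones stays open: that list lay at percentile 36.9 in the transgenic line against wild type, but its members went both ways (SD 0.56) and hsf-1 itself was higher in that line. Reads moved between hsp-16 copies are argued against by the sum over 6 copies, 102.1 in wild type and 12.23 in the transgenic line. That is a ratio of 8.35, and the sum in the mutant was lower still, at 1.27. The sum rests mostly on hsp-16.2, since hsp-16.1, hsp-16.11, hsp-16.48 and hsp-16.49 were listed at 0 in every genotype. Reads left out of all copies would not show in it. One uneven wild-type library may hold most of the signal, and the q of 0.437 for hsp-16.2 in the authors' deposited table does not decide it without values per library. A milder exposure of some larvae, and a lower stress response of the transgenic line, stay open and untested.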

How the results depend on the processing

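The alternatives that leave out genes listed at 0, or genes in a shared locus, or that adjust p-values among genes with an FPKM of at least 5, were chosen only after the data were seen.

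Of 735 called genes in the mutant against wild type, 353 passed at a q of at most 0.01 (190 higher), where the stricter threshold itself lowers the count, and the other alternatives gave 590 to 735. The share nearer to wild type in the transgenic line was 80.5% among those 353, the cause was not tested, and 69.1% to 72.1% under the other alternatives. Genes with intervals apart numbered 159 to 179 for the mutant against the transgenic line and 73 to 86 for the transgenic line against wild type. The log2 difference of hsf-1 lay between −0.24 and −0.21. Of the named genes that passed, 44 no longer passed at a q of at most 0.01 and 20 had an absolute log2 fold change under 1.

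The 30 list medians in the mutant against wild type kept their side of percentile 2.5 and of the matching upper bound with a pseudocount of 0.1 and with centring. Elsewhere the following changed side, and the cause was not tested. Without a filter, histones (0, percentile 50), moulting (0.16, 94.9) and C-type lectins (0, 42.7) came to lie inside and neuropeptides (0.29, 99.7) outside, and with a minimum FPKM of 5 moulting (0.22, 94.4) lay inside. With lists matched on length too, the proteasome (0.29, 96.0) and moulting (0.28, 95.9) lay inside, and ribosomal proteins (−0.0133, 97.53), neuropeptides (0.30, 99.1) and glycolysis (−0.17, 1.71) outside. With unmatched lists, the proteasome (0.29, 83.2), moulting (0.28, 90.1), the P450 and transferase list (−0.0163, 4.17) and autophagy (0.43, 95.3) lay inside. Among genes in a locus of their own, translation factors (−0.13, 8.22), the proteasome (0.29, 93.6), C-type lectins (0.44, 91.5) and autophagy (0.35, 95.5) lay inside, and the 3 heat-inducible genes left (1.17, 98.2) outside. In the other 2 comparisons, 19 of the list results under these settings came to lie inside and 8 outside. Those that came to lie inside were heat-inducible genes, ribosomal proteins, neuropeptides, the intestine and C-type lectins in the transgenic line against wild type, and histones, collagens, antimicrobial effectors and autophagy in the mutant against the transgenic line.

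No paired analysis was possible because the tables used here hold 1 value per genotype, with no column per replicate. For the same reason the leave-one-out fits, the linear model per replicate, the replicate block and count-based tools were not run. A q of at most 0.01 and another adjustment could not be applied to the comparisons for which no test is used here.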

Other observations

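The test of vhl-1 and all groups and genes of this part were chosen only after the values were seen.

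Several genes that make and spend methyl groups fell in the mutant. Of 12 genes picked for methionine, glycine and phosphocholine metabolism, 7 fell, 0 rose and 5 did not pass in the authors' deposited table, with a median log2 difference of −1.39, and of −0.01 in the transgenic line against wild type. The 7 include the nuclear hormone receptor gene nhr-114, while gcsh-2, which fell in the authors' deposited table too, was not among the 12. The S-adenosylhomocysteine hydrolase gene ahcy-1 was at 4664 (interval 3001 to 6326) in wild type, 1319 (763 to 1876) in the mutant and 5815 (4105 to 7525) in the transgenic line, and the S-adenosylmethionine synthetase gene sams-1 at 1235 (788 to 1681), 355 (202 to 508) and 1361 (857 to 1865). The glycine cleavage gene gcsh-1 fell 6.35-fold, and the serine hydroxymethyltransferase gene mel-32 fell 2.59-fold, while mthf-1 was at 256 and 258.7. No random-list test was run for this group. The 5 genes picked from the propionate shunt fell in the authors' deposited table, with a median of −1.57 and of −0.17 in the transgenic line. Besides acdh-1 and ech-6 they were hach-1, from 272 (138 to 406) to 91.3 (36.5 to 146), hphd-1 and alh-8.

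Genes for mitochondrial ribosomal proteins lay lower in the mutant. Of 40 mrpl genes 3 fell and 0 rose in the authors' deposited table, with a median of −0.61, and of 28 mrps genes 5 fell and 0 rose, with a median of −0.65, both at percentile 0. In the transgenic line the medians were −0.09 and −0.18, yet 5 of the 8 genes that fell stayed nearer to the mutant on the log2 scale, such as mrpl-20 (−2.07, beside −2.34 in the mutant) and mrps-12 (−1.75, beside −1.86). The gene mrps-28 was at 303.6 (119.3 to 466) in wild type, 71.6 (21.6 to 121) in the mutant and 134.6 (47.3 to 219.8) in the transgenic line. The F-box genes of the fbxa family, 79 tested, had a median of 0.99 at percentile 100 in the mutant and −0.00 in the transgenic line, with 4 that rose and 1 that fell in the authors' deposited table and many at low values. These came from a scan of 125 families named by symbol, of which 11 lay below percentile 2.5 and 15 above the matching upper percentile, where 6.25 in both tails together would lie there by chance.

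The CCT chaperonin folds tubulin and actin. Of 14 tubulin and actin genes, 3 rose and 0 fell in the authors' deposited table: tbb-6, the beta-tubulin gene ben-1, from 14.6 (3.34 to 25.8) to 42.2 (15.9 to 68.5), and the alpha-tubulin gene tba-1, from 476 (265 to 686) to 799 (459 to 1139.7). The abundant actin gene act-4 was at 3201 (1982 to 4406) in wild type and 4717 (3116 to 6317) in the mutant, with a q of 0.097 in the authors' deposited table. In the transgenic line ben-1 was at 28.1 (8.95 to 47.1), tba-1 at 734 (430 to 1039) and act-4 at 4177 (2592 to 5730), each nearer to the mutant on the scale of log2(FPKM + 1), and tbb-6 at 2.14 (0 to 4.22), near wild type.

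Some called genes, such as hpl-2, had nearly the mutant level in the transgenic line. The heterochromatin protein gene hpl-2 was at 214 (63.5 to 365) in wild type, 70.7 (17.2 to 124) in the mutant and 56.8 (11.8 to 102) in the transgenic line. At a mean FPKM of at least 100, the 5 genes with intervals apart in the transgenic line against wild type were C48B4.6, at 396 against 7.43, F52A8.3, at 241 against 2.97, and rhr-1, patr-1 and fcmt-1. The cell death gene egl-1 was at 1.66 (0 to 3.82) in wild type, 23.2 (3.82 to 42.4) in the mutant and 1.15 (0 to 2.29) in the transgenic line, with a q of 0.155 in the authors' deposited table.

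Some targets of the hypoxia factor HIF-1 rose in the mutant. Of 8 tested, 4 rose, 0 fell and 4 did not pass in the authors' deposited table, among them rhy-1, from 9.71 (0.263 to 19.4) to 103.6 (47.3 to 159.8), and nhr-57, from 20.3 (4.52 to 36.1) to 118 (53.97 to 182). The gene vhl-1, whose product marks HIF-1 for degradation, fell from 43.9 (9.35 to 78.5) to 8.93 (1.07 to 16.7), while hif-1 was at 235 and 281. As a hypothesis, less vhl-1 RNA may alone account for the rise of the 4 targets. In the transgenic line vhl-1 was as low, at 5.64 (0.153 to 11.04), yet the median log2 difference of the 4 targets from wild type was −0.0545 there, against 2.07 in the mutant. They went both ways in the transgenic line, egl-9 (0.97) and phy-2 (0.45) above wild type and rhy-1 (−0.56) and nhr-57 (−1.84) below, and they were picked for having risen in the mutant, so some return is built in. In simulations without rescue, such picking alone undid a median of 0.19 of a change, and with this taken off the gap is 1.72. The SD of the 4 differences, 2.06, is the spread between unlike genes and no error of the gap, so it decides nothing. The intervals of the mutant and the transgenic line were apart for rhy-1 and nhr-57, and overlapped for egl-9 and phy-2. For the 4 targets as a set, the hypothesis stays open.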
